A study of Mus musculus with 12 samples.

How the data were processed

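Frontal cortex was taken from 12 male F1 hybrid mice of a pair of inbred strains, 14 weeks old, with 4 animals in each of 3 groups. The labels call the groups WT, GluN1 and GluN1Cre, and the series title speaks of wild-type mice, Grin1 knockdown and Grin1 Cre rescue; they are called wild type, knockdown and rescue here. Every animal received tamoxifen, a ligand that activates inducible forms of the Cre recombinase, from 10 weeks of age: 6 mg by gavage and about 14 mg in chow. Per the labels' protocols, total RNA was isolated with Tri Reagent from the frozen tissue and polyadenylated RNA was selected for the libraries.

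Reads were processed on a Galaxy server, per the series' design text. The submitters' processing notes name FastQC 0.65, TopHat, TopHat2 2.1.0, Cufflinks 2.2.1.0, Cuffdiff 2.2.1.3 and the builds mm10 and GRCm38. The authors deposited 3 Cuffdiff tables, each comparing a pair of groups. Per the file headers, each table gives for every assembled gene model an FPKM (fragments scaled by transcript length and library size) per group, which the authors' Cuffdiff run estimated over the libraries of the group. Per the file headers, the tables also hold the log2 fold of the groups, a test statistic (a score with no fixed range), a p-value and a q-value, all made by the authors with Cuffdiff. The deposited q-values differed by at most 5.14e-07 from Benjamini-Hochberg values recomputed over the tested models, and the smallest deposited p was 5e-05. The tables were assembled and normalised separately, so tests stay within a table, and levels set side by side across tables carry that limit.

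The tables hold no values per animal, so depth per sample is unknown and no spread between animals, paired fit or left-out animal could be computed here. The p-values and q-values are those of the authors' test. The table of rescue against knockdown had passed through a spreadsheet: 498 fold cells could not be read and 27 symbols had become dates, of which 26 were restored from the locus in the other tables. All log2 folds printed here were therefore recomputed from the authors' deposited FPKM values of the groups, in all 3 tables.

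A gene model was called changed by the threshold in the series' design text (p under 0.05 and q under 0.10) among the models Cuffdiff tested. Assembled models carry the symbols the authors' tables give; a gene assembled into several models counts once per model. Among the tested models with a single symbol, 13211 of 14512, 13235 of 14544 and 13201 of 14500 (knockdown against wild type, rescue against knockdown, rescue against wild type) were found by symbol in the GENCODE M21 annotation of GRCm38. The genes named were Grin1 and the other NMDA receptor subunits, the 12 largest rises and 12 largest falls among called models with a mean FPKM of at least 1 and a single symbol, and up to 4 called members of each gene list by smallest q; any other gene was chosen after its values were seen. A few genes and 1 list that this rule names are not reported here.

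The choices of groups, threshold, gene lists, naming rule and most other settings were made before the data were examined. For each of the 33 gene lists, called members were counted among models with a mean FPKM of at least 1, and their number was compared with that among all other such models by a one-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 32 lists that had measured members. The list of mitochondrially encoded genes had 0 measured members. A list's median log2 fold was also placed as a percentile among 10000 random lists of the same size matched on mean FPKM in 20 bins. Genes are not independent replicates, so these list tests compare genes, not animals. Called genes within 10 Mb of Grin1 and of Gt(ROSA)26Sor, a locus often used for Cre alleles and not named in the labels, were counted with a two-sided Fisher's exact test.

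Models were matched across the 3 tables by symbol and overlapping locus, and unnamed models by an overlap of at least 80% of their span. This gave 22608 models, of which 13907 were tested in all tables. The folds of the 3 comparisons should add up, and the median absolute error of that sum was 0.01 on the log2 scale. Comparisons that share a group share its chance values, so overlaps are given beside the number for independent lists and beside 1000 simulated sets of unchanged groups. Since unchanged groups hold almost no calls, 1000 sets with the knockdown folds kept, called at the largest called p of each table, were added after seeing the data. The simulated spread of each gene came from its fold and test statistic; since the deposited statistic was 0.497 of the normal deviate of the deposited p in the table of knockdown against wild type, a spread scaled by that ratio was added after seeing the data.

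The list, overlap and neighbour steps were tested on simulated data built on the 13918 models of knockdown against wild type with a mean FPKM of at least 1. Every simulated gene had the same normal error, close to the spread of the observed folds, and calls used that known error. With 200 changed genes, 97% of those with a log2 change of 0.5 and 100% of those with a log2 change of 1 were recovered. Of the calls 8.37% were unchanged genes, and 4.5% of random lists had a Fisher p under 0.05. These rates follow from the simulated error and do not give the power of the authors' Cuffdiff test. Alternatives covered the q threshold, no adjustment, filters on FPKM and fold, p recomputed from the test statistic, centred folds, TPM rescaling, a pseudocount of 1, fewer expression bins and windows of 5 and 20 Mb. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.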

Results

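Polyadenylated RNA of the frontal cortex was sequenced in 12 male mice, 4 wild type, 4 Grin1 knockdown and 4 Grin1 knockdown with Cre rescue. Grin1 encodes the subunit that every NMDA-type glutamate receptor needs. All animals received tamoxifen as adults, and the rescue group carried Cre. The design therefore asks which transcripts differ when Grin1 is low and which of them move back when it is partly restored in adult animals. By the group names no other group carried Cre, so effects of Cre itself cannot be told apart from those of restored Grin1. The authors' tables hold 1 FPKM value per group and their own test, so the values below carry no spread between animals and read depth is unknown. Cuffdiff tested 18417 gene models for knockdown against wild type, 18430 for rescue against knockdown and 18429 for rescue against wild type. The median log2 fold of models with a mean FPKM of at least 1 was -0.01, -0.00 and -0.01 in that order. Medians of 21, 17 and 20 of the 32 gene lists lay outside the middle 95% of matched random lists, a count chosen after seeing the data. A percentile near 0 or 100 is therefore common here and compares genes, not animals.

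In the knockdown cortex Grin1 lay at 56.7 FPKM against 138 FPKM in wild type, 41.0% of the wild-type level (log2 fold -1.28, q = 0.00456 in the authors' deposited table). Immediate early genes fell with it: Arc, whose product acts at excitatory synapses, had a log2 fold of -0.68, and the transcription factors Egr2 and Junb -0.78 and -0.50 (each q = 0.00456 in the authors' deposited table). Genes of inhibitory neurons and peptide signalling rose, among them Calb2 (calretinin, 18.4 to 46.9 FPKM), Npy (neuropeptide Y, 119 to 186 FPKM) and Scg2 (secretogranin II, 93.1 to 156 FPKM). Markers of the olfactory bulb rose and markers of striatal medium spiny neurons fell in the same libraries. In all, 464 models were called, 306 higher and 158 lower in the knockdown.

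Grin1 lies on the minus strand of chromosome 2 of GRCm38, from 25287840 to 25319163 as assembled by the authors in this table; GENCODE M21 lists it as ENSMUSG00000026959, a protein-coding gene from 25291181 to 25319187. The other NMDA receptor subunits tested in this table did not pass. Grin2b and Grin3b have no tested model in it. Log2 folds were -0.05 for Grin2a, 0.15 for Grin2c, 0.12 for Grin2d and -0.15 for Grin3a. Of the 5 NMDA receptor models measured, 1 fell, 0 rose and 4 were not called, 1 was called when adjusted over the list alone, and the list's adjusted p was 0.284 by Fisher's exact test. None of the 14 AMPA and kainate receptor models or the 7 metabotropic glutamate receptors was called by Cuffdiff, over all genes or adjusted over the list alone, at list medians of -0.03 and 0.04. The 39 models of postsynaptic density and NMDA receptor signalling had 0 calls over all genes and 4 adjusted over the list alone. Of their folds 33 were negative, and the median of -0.09 lay at percentile 0 of matched random lists. Among 24 presynaptic release models 2 fell and 22 were not called: Cplx2 (complexin 2) went from 252 to 185 FPKM and Stx1a (syntaxin 1A) from 129 to 109 FPKM. Adjusted over the list alone 2 were called, and the list's adjusted p was 0.284 by Fisher's exact test.

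Of 33 activity-regulated models, 10 fell, 1 rose and 22 were not called, and 20 were called when adjusted over the list alone. The list held more calls than other genes (adjusted p = 7.62e-09, Fisher's exact test) and had a median log2 fold of -0.20. Arl4d fell by 0.53 and Egr2 from 2.14 to 1.25 FPKM. The member that rose was a model of Bdnf, a neurotrophin gene with 2 models in the table, by 0.32 on the log2 scale (chosen after its values were seen). Of 20 excitatory layer marker models, 2 fell, 18 were not called and 8 were called when adjusted over the list alone (adjusted p = 0.242, Fisher's exact test). Of their folds 17 were negative, and the median of -0.15 lay at percentile 0 of matched random lists. Those that fell were Crym, a thyroid hormone binding protein, from 64.7 to 45.9 FPKM, and Fezf2, a transcription factor of deep-layer neurons, from 12.6 to 9.40 FPKM.

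Striatal medium spiny neuron markers moved down beside the activity-regulated genes: 6 of 15 fell, 0 rose, 9 were not called, and 10 were called when adjusted over the list alone (adjusted p = 9e-06, Fisher's exact test; median log2 fold -0.31). Log2 folds were -0.62 for Adora2a, an adenosine receptor, -0.51 for the dopamine receptor Drd1a and -0.38 for the sodium channel subunit Scn4b (1 of 2 models). The dopamine receptor Drd2 fell by 0.65 (q = 0.00833 in the authors' deposited table). Among 13 dopamine and serotonin receptors, Drd1a and Drd2 were the 2 that fell, 11 were not called, and 3 were called when adjusted over the list alone (adjusted p = 0.132, Fisher's exact test).

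Of 19 interneuron marker models, 8 rose, 0 fell and 11 were not called, with 10 called when adjusted over the list alone (adjusted p = 1.11e-07, Fisher's exact test; median log2 fold 0.23). Besides Calb2 and Npy, Reln, an extracellular signalling protein, rose by 0.57 and Crhbp, which binds corticotropin-releasing hormone, by 0.45. Of 18 neuropeptide genes, 8 rose and 10 were not called, with 9 called when adjusted over the list alone (adjusted p = 8.74e-08, Fisher's exact test). The interneuron and neuropeptide lists each have 6 members on other lists, and Npy and Sst count among the called members of both. Crh (corticotropin-releasing hormone) rose from 4.28 to 10.5 FPKM and Trh (thyrotropin-releasing hormone) from 2.92 to 8.61 FPKM. In the GABA list 3 of 19 rose and 16 were not called, with 3 called when adjusted over the list alone (adjusted p = 0.0484, Fisher's exact test): Gad1 and Gad2, which make GABA, by 0.33 and 0.25, and the transporter Slc6a11 by 0.39. Beside these groups, 8 of 11 olfactory bulb marker models rose, 0 fell and 3 were not called, with 9 called when adjusted over the list alone (adjusted p = 1.16e-09, Fisher's exact test; median log2 fold 1.04). Th (tyrosine hydroxylase) went from 4.52 to 12.5 FPKM and Eomes (1 of 2 models) from 1.17 to 5.35 FPKM, and the merged model Doc2g,Nudt8 rose as well. In the hypothalamic and thalamic list, Calb2 and Trh were the 2 of 7 that rose and 5 were not called, with 2 called when adjusted over the list alone (adjusted p = 0.0484, Fisher's exact test).

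Of 16 glucocorticoid-responsive genes, 3 rose, 1 fell and 12 were not called, with 8 called when adjusted over the list alone (adjusted p = 0.00321, Fisher's exact test). The metallothioneins Mt1 and Mt2 rose by 0.28 and 0.47 and the cell cycle inhibitor Cdkn1a by 0.35, while the clock gene Per1 fell by 0.38. Meningeal and fibroblast markers rose as well: 5 of 13 rose, 8 were not called, and 9 were called when adjusted over the list alone (adjusted p = 7.54e-05, Fisher's exact test; median log2 fold 0.37), among them Aldh1a2 by 0.52 and Igfbp2 by 0.38. Astrocyte markers Gfap (34.6 to 54.0 FPKM) and Aqp4 (23.5 to 28.8 FPKM) rose, 11 of the 13 were not called, and 3 were called when adjusted over the list alone (adjusted p = 0.132, Fisher's exact test). All 13 folds were positive, with a median of 0.14 at percentile 100 of matched random lists.

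The largest rises included Rmrp (1.43 to 9.32 FPKM) and Rpph1 (1.24 to 7.31 FPKM), RNA components of ribonucleases that carry no poly(A) tail, with q = 0.022 and q = 0.0117 in the authors' deposited table. S100a5, a calcium-binding protein gene, rose by 2.63, Tbx21 by 2.58, Shisa3 by 2.30, Ush1g by 2.19, Kcnk15 by 2.01, Ms4a15 by 1.97, Scgn by 1.96 and Ppm1j by 1.68 (each q = 0.00456 in the authors' deposited table). These genes are not on the bulb list, and whether a share of bulb tissue accounts for them was not tested in any comparison. Besides Grin1, the largest falls were Myoc with a log2 fold of -1.37, Gkn3 (-1.18), Egr2, Tnnc1 (-0.77), the ferritin gene Ftl1 (-0.76), Vwa3a (-0.72), Nxph2 (-0.68), Arc, Drd2, the neuroglobin gene Ngb (-0.64) and Zfp189 (-0.63). The GABA list call was lost at q under 0.05, where 2 members were called, and both it and the hypothalamic and thalamic call were lost without the FPKM filter (adjusted p = 0.0518 and 0.105, Fisher's exact test) and, in tests chosen after seeing the data, without bulb and striatal list genes (0.0663 and 0.374) and with centred folds and a rescaled statistic (0.0565 each). With centred folds and p taken from the deposited test statistic, 42 models and 4 of the lists passed; that statistic is 0.497 of the normal deviate of the deposited p, which alone lowers these counts.

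**Figure D1:**
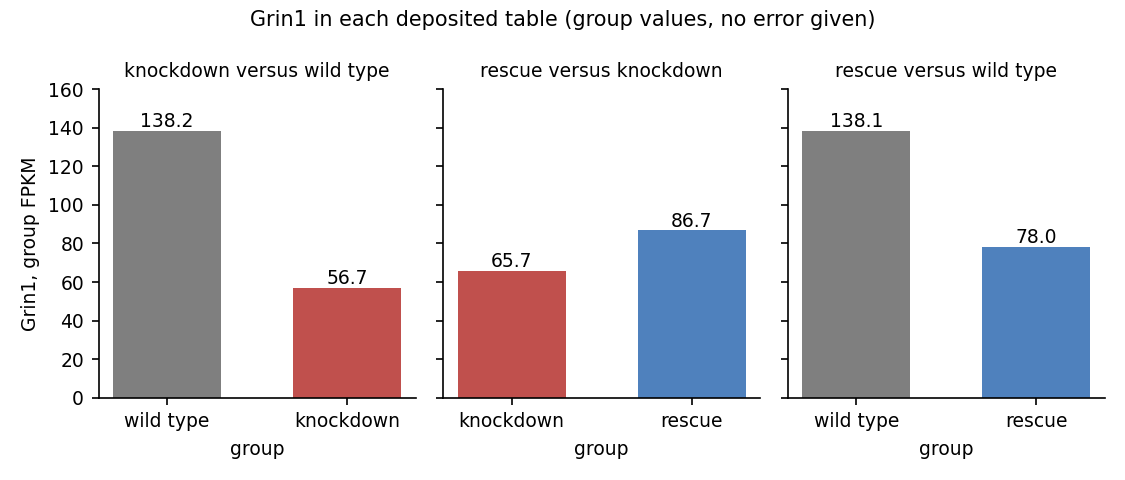
Grin1 level in FPKM (vertical axis, from 0) for the groups of each of the 3 deposited comparisons, with bars for the authors' group values and no error bars because the tables hold no values per animal. Grin1 stood at 56.7 FPKM in the knockdown against 138 FPKM in wild type, and at 86.7 FPKM in the rescue against 65.7 FPKM in the knockdown, and at 78.0 FPKM in the rescue against 138 FPKM in wild type.

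In the rescue cortex Grin1 rose to 86.7 FPKM from 65.7 FPKM in the knockdown, 1.32 times the knockdown level (log2 fold 0.40, q = 0.038 in the authors' deposited table). The knockdown level differs from the 56.7 FPKM of the other table; the tables were assembled and normalised separately. Falls outnumbered rises, with 103 of 127 called models lower and 24 higher in the rescue group. Glucocorticoid-responsive genes fell, including Fkbp5, a co-chaperone of steroid receptors (17.2 to 11.9 FPKM), and Mt2 (358 to 242 FPKM). Olfactory bulb markers fell, as did the peptide genes Trh, Crh and Scg2 among those called higher in the knockdown, while haemoglobin transcripts rose.

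Of 16 glucocorticoid-responsive genes, 7 fell, 0 rose and 9 were not called, with 8 called when adjusted over the list alone (adjusted p = 2.96e-10, Fisher's exact test; median log2 fold -0.36). Log2 folds were -0.56 for Hif3a, -0.46 for Tsc22d3 (the glucocorticoid-induced leucine zipper) and -0.96 for the lipid droplet gene Plin4. Of 14 astrocyte marker models, 2 fell and 12 were not called, with 5 called when adjusted over the list alone (adjusted p = 0.0288, Fisher's exact test; median log2 fold -0.15): Gfap went from 54.1 to 42.4 FPKM and Gjb6 (1 of 2 models) from 33.3 to 25.6 FPKM. Blood cell markers moved the other way: 3 of 7 models rose, 4 were not called, and 4 were called when adjusted over the list alone (adjusted p = 0.000136, Fisher's exact test; median log2 fold 0.54). Those were both models of Hba-a1,Hba-a2 (log2 folds 0.65 and 1.03), which share reads between near-identical genes, and Beta-s (0.38).

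Of 18 neuropeptide genes, 5 fell, 0 rose and 13 were not called, with 11 called when adjusted over the list alone (adjusted p = 2.5e-06, Fisher's exact test; median log2 fold -0.16). Log2 folds were -0.86 for Trh, -0.72 for Crh, -0.63 for Cartpt and -0.36 for Penk (the enkephalin precursor). Of 18 interneuron marker models, 2 fell and 16 were not called, with 5 called when adjusted over the list alone (adjusted p = 0.0407, Fisher's exact test; median log2 fold -0.16): Calb2 (-0.67) and Dlx2 (-0.58, 1 of 2 models). Beside them, 7 of 12 olfactory bulb marker models fell, 0 rose and 5 were not called, with 8 called when adjusted over the list alone (adjusted p = 4.21e-11, Fisher's exact test; median log2 fold -0.53), Th (-0.77), Eomes (-0.82, 1 of 2 models) and Doc2g,Nudt8 among them. Calb2 and Trh were again the 2 of 7 called in the hypothalamic and thalamic list, both lower, with 2 called when adjusted over the list alone (adjusted p = 0.00828, Fisher's exact test). In the striatal list 1 of 15, Penk, fell and 14 were not called, with 2 called when adjusted over the list alone (adjusted p = 0.33, Fisher's exact test). Of these folds 13 were negative, and the median of -0.12 lay at percentile 0 of matched random lists, while Grin1 rose in this comparison. Slc6a11 was the 1 of 19 GABA genes called, with a log2 fold of -0.31 and 2 called when adjusted over the list alone (adjusted p = 0.377, Fisher's exact test).

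None of the 32 activity-regulated models was called between rescue and knockdown over all genes, and 1 was called when adjusted over the list alone (adjusted p = 1, Fisher's exact test; median log2 fold -0.06). Of these folds 25 were negative, and the median lay at percentile 0.06 of matched random lists. Among 7 NMDA receptor models with a mean FPKM of at least 1 Grin1 was the 1 that rose, and 1 was called when adjusted over the list alone (adjusted p = 0.194, Fisher's exact test). The others had log2 folds of 0.07 for Grin2a (and -0.01 for a further model below 1 FPKM, outside the 7), 0.14 and 0.52 for the 2 models of Grin2b, -0.18 for Grin2c, -0.05 for Grin2d and 0.23 for the merged model Grin3a,Ppp3r2. Nos1, the neuronal nitric oxide synthase, was the 1 of 39 postsynaptic models that rose, by 0.42, with 1 called when adjusted over the list alone (adjusted p = 0.662, Fisher's exact test). Of these folds 33 were positive, and the median of 0.06 lay at percentile 100 of matched random lists. None of 12 AMPA and kainate models, 7 metabotropic glutamate receptors, 25 presynaptic models or 13 dopamine and serotonin receptors was called by Cuffdiff over all genes, and 0, 0, 0 and 1 were called when adjusted over the list alone. In the excitatory layer list 0 of 21 models were called over all genes and 1 when adjusted over the list alone, and in the meningeal and fibroblast list 0 of 13 and 2. Their medians were 0.04 and -0.14, at percentiles 99.5 and 0.02 of matched random lists.

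The RNAs without a poly(A) tail were among the largest falls, Rpph1 at a log2 fold of -2.39, Rmrp at -2.05 and the ribosomal precursor Rn45s at -0.98 (1176 to 596 FPKM). Others were S100a5 (-1.18), Klhl30 (-1.08), Ush1g (-1.08), Tbx21 (-1.02), Shisa3 (-0.98) and 1 of 2 models each of 2610528E23Rik (-1.05) and Zc3h7a (-0.87). The largest rise was in 1 of 2 models of Rplp2, from 2.67 to 41.6 FPKM, which is reported as uncertain since reads of 1 gene are split between models. Gh (growth hormone) rose by 1.19, Gkn3 by 1.18, Myoc by 0.96, Adamts2 by 0.78, Vwa3a by 0.51, Spag5 by 0.40, Rxfp1 by 0.37 and the non-coding RNA Miat by 0.32. The interneuron and the hypothalamic and thalamic calls were lost without the members shared with the bulb and striatal lists, a test chosen after seeing the data, where 1 member was called in each (adjusted p = 0.402 and 0.234, Fisher's exact test), and the interneuron call also with centred folds and a rescaled statistic (0.0503), chosen likewise. With centred folds and p from the deposited test statistic, 15 models and 0 lists passed.

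In the rescue cortex Grin1 lay below wild type, at 78.0 FPKM against 138 FPKM, 56.5% of the wild-type level (log2 fold -0.82, q = 0.0098 in the authors' deposited table). This comparison asks which differences from wild type are present after Cre rescue. Immediate early genes were lower than in wild type, with Arc at 20.6 against 31.8 FPKM and Nr4a1, a nuclear receptor, at 23.5 against 34.6 FPKM. Dopamine receptor transcripts were lower too, with log2 folds of -1.18 for Drd2 and -0.59 for Drd1a (each q = 0.0098 in the authors' deposited table). In all, 155 models were called, 67 higher and 88 lower in the rescue group.

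Of 33 activity-regulated models, 11 fell, 0 rose and 22 were not called, with 16 called when adjusted over the list alone (adjusted p = 1.2e-13, Fisher's exact test; median log2 fold -0.18). Log2 folds were -0.91 for Egr2 and -0.59 for Junb. Striatal markers were lower as well: 9 of 15 fell, 0 rose and 6 were not called, with 13 called when adjusted over the list alone (adjusted p = 8.73e-14, Fisher's exact test; median log2 fold -0.42), among them Adora2a (-0.91) and Rgs9 (-0.61), a regulator of G protein signalling. Drd1a and Drd2 were also the 2 of 13 dopamine and serotonin receptors that fell, with 2 called when adjusted over the list alone (adjusted p = 0.0271, Fisher's exact test). Of 21 excitatory layer marker models, Crym and Nr4a2 fell, with log2 folds of -0.38 and -0.53, 19 were not called and 8 were called when adjusted over the list alone (adjusted p = 0.0617, Fisher's exact test). Of these folds 15 were negative, with a median of -0.08 at percentile 0.08 of matched random lists. Per1 was the 1 of 16 glucocorticoid-responsive genes called, with a log2 fold of -0.43, and 6 were called when adjusted over the list alone (adjusted p = 0.33, Fisher's exact test). Of these folds 15 were negative, and the median of -0.21 lay at percentile 0 of matched random lists.

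Of 18 neuropeptide genes, 5 rose, 1 fell and 12 were not called, with 10 called when adjusted over the list alone (adjusted p = 9.97e-08, Fisher's exact test; median log2 fold -0.01). Npy went from 118 to 166 FPKM, Scg2 from 91.2 to 125 FPKM, and Adcyap1, the precursor of the peptide PACAP, rose by 0.50, while Penk fell by 0.42. Of 18 interneuron marker models, Calb2, Npy and Reln were the 3 that rose, by 0.64, 0.49 and 0.39, and 15 were not called, with 5 called when adjusted over the list alone (adjusted p = 0.00348, Fisher's exact test; median log2 fold 0.00). Bulb markers rose beside them: 6 of 11 rose, 0 fell and 5 were not called, with 8 called when adjusted over the list alone (adjusted p = 3.5e-09, Fisher's exact test; median log2 fold 0.48), among them Eomes by 1.29, Th by 0.67 and Pbx3 by 0.48. Calb2 and Trh were the 2 of 7 called in the hypothalamic and thalamic list, both higher, with 2 called when adjusted over the list alone (adjusted p = 0.00866, Fisher's exact test). Of 7 blood cell models 3 rose and 4 were not called, with 6 called when adjusted over the list alone (adjusted p = 0.000194, Fisher's exact test; median log2 fold above 100% of matched random lists): Hba-a1,Hba-a2 in both models, by 1.03 and 1.05, and Beta-s by 0.53.

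Among 6 NMDA receptor models with a mean FPKM of at least 1 Grin1 was the 1 called, and 1 was called when adjusted over the list alone (adjusted p = 0.165, Fisher's exact test). The log2 folds of the others were 0.02 for Grin2a (and 0.16 for a further model below 1 FPKM, outside the 6), 0.16 for Grin2b, -0.04 for Grin2c, 0.05 for Grin2d and 0.08 for Grin3a. Nos1 rose by 0.48 as the 1 of 39 postsynaptic models called, and Cplx2 fell from 250 to 172 FPKM as the 1 of 25 presynaptic models, with 1 called in each list when adjusted over the list alone (adjusted p = 0.595 and 0.432, Fisher's exact test). The postsynaptic median was -0.05, at percentile 8 of matched random lists. Gfap rose by 0.28 as the 1 of 14 astrocyte models called, with 1 called when adjusted over the list alone (adjusted p = 0.33, Fisher's exact test). None of 12 AMPA and kainate models, 7 metabotropic glutamate receptors, 19 GABA genes or 12 meningeal and fibroblast markers was called by Cuffdiff over all genes, and 0, 0, 2 and 4 were called when adjusted over the list alone. Of the 12 meningeal and fibroblast folds 11 were positive, and their median of 0.15 lay at percentile 100 of matched random lists.

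The largest rises were in a model of Rplp2 (3.48 on the log2 scale, uncertain as above), S100a5 (1.43), Scgn (1.37), Shisa3 (1.33), Eomes, Ms4a15 (1.10), Ppm1j (1.08), the procollagen protease Adamts2 (1.01), follistatin (Fst, 0.97), the water channel Aqp1 (0.85), Xlr3b (0.80) and the receptor Lgr5 (0.77). Besides Drd2, Egr2, Adora2a and Grin1, the largest falls reported here were in Lrg1, Lrrc10b (-0.81), Dct (-0.72), Folh1 (-0.68), B230217O12Rik (-0.65), Tnnc1 (-0.63) and Alox12b (-0.63). Without the members shared with the bulb and striatal lists, a test chosen after seeing the data, the interneuron, dopamine and hypothalamic calls were lost, with 2, 0 and 1 members called. With centred folds and p from the deposited test statistic, 18 models and 0 lists passed.

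**Figure D2:**
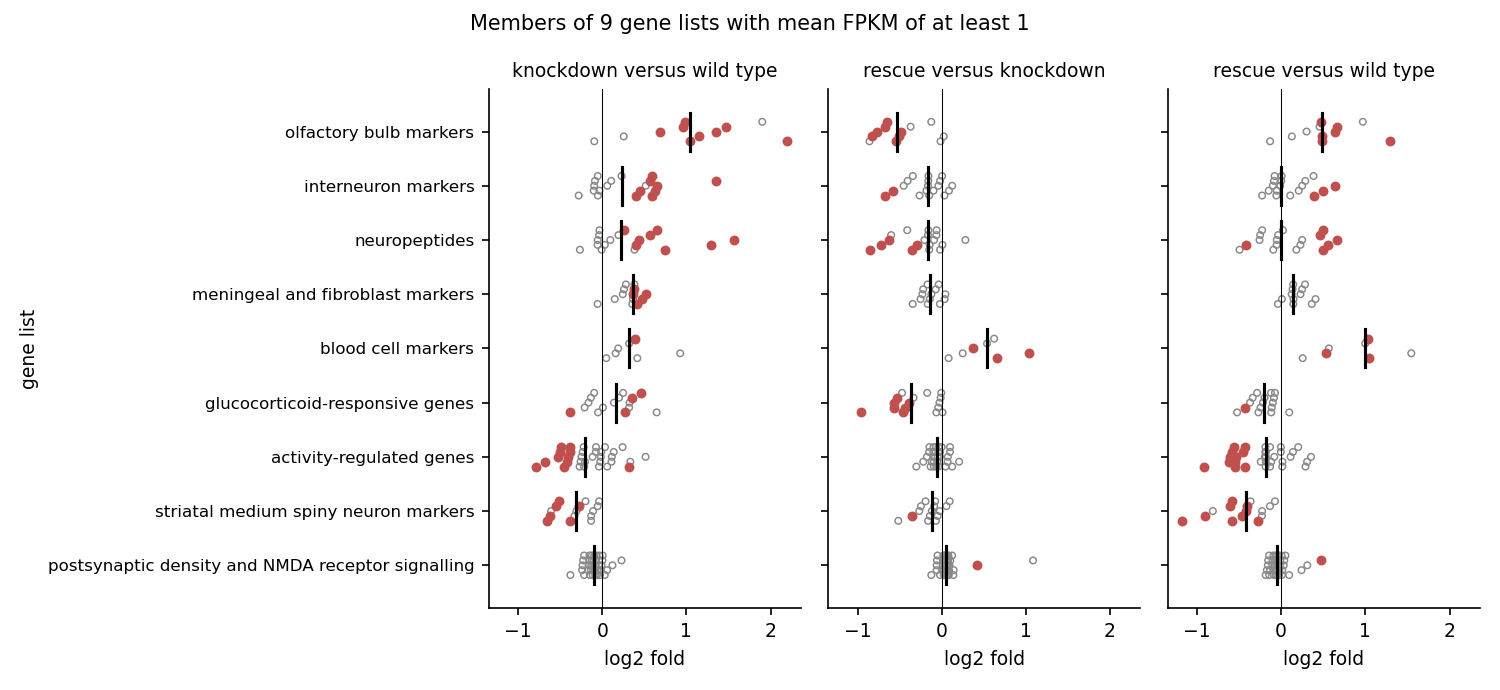
Log2 fold (horizontal axis) of each member model with a mean FPKM of at least 1, by gene list (vertical axis), in the 3 comparisons; filled red points were called, open grey points were not, and black bars are list medians. Bulb markers had medians of 1.04, -0.53 and 0.48, and activity-regulated genes -0.20, -0.06 and -0.18, for knockdown against wild type, rescue against knockdown and rescue against wild type.

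Set side by side, the comparisons show which knockdown changes were called back in the rescue group and which were called alike in both groups. Arc, Egr1, Egr2, Fos, Junb, Nr4a1, Nr4a3, Per1, Drd1a, Drd2, Adora2a, Npy and Reln were called in the same direction against wild type in knockdown and rescue, and not called between them. Of these, Drd1a, Drd2 and Adora2a are striatal list members, and a different share of striatal tissue was not tested for them. Mt1, Mt2, Cdkn1a, Rmrp, Rpph1, Gkn3, Myoc and Slc6a11 were called in the knockdown, called oppositely in rescue against knockdown, and not called between rescue and wild type. Grin1 was called in all 3 comparisons, lower in knockdown and part of the way back in rescue. A missed threshold does not show that levels were equal.

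Among 13907 models tested in all tables, 388, 101 and 135 were called in knockdown against wild type, rescue against knockdown and rescue against wild type. Of the knockdown calls, 67 were also called in the opposite direction in rescue against knockdown, 60 of them higher and 7 lower in the knockdown, and 2 were called in the same direction. Independent lists would share 1.73. Simulated groups without any change gave 0 at most in 1000 sets, but hardly any gene is called in them. Against wild type, 97 models were called in the same direction in both groups and 0 in opposite directions, beside 1.82 for independent lists and a highest count of 1 in sets without any change. A simulation chosen after seeing the data kept the knockdown folds, gave the rescue comparison no effect and called at the largest p called in each of the authors' deposited tables. Over 11622 models it gave a mean of 1.42 and at most 6 opposite calls beside 58 observed, and a mean of 1.64 and at most 8 calls in the same direction beside 86. It held a mean of 591 and 590 knockdown calls beside 315 observed, nearly double, and of 7.91 and 9.43 calls in the second comparison beside 88 and 121 observed. Of the second calls 17.9% and 17.4% overlapped beside 65.9% and 71.1% observed. The simulation does not separate return from other changes in the rescue group. The wild-type and knockdown libraries could not be split, so part of either excess may come from shared libraries.

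By class, 42 models were called in knockdown, called back in rescue and not called between rescue and wild type, 25 were called in all 3 comparisons with a partial return, and 70 were called alike in both groups and not between them. Of these 70, 25 were higher and 45 lower than wild type. The lower ones include the striatal list members Drd1a, Drd2, Adora2a and Ppp1r1b, for which the share of striatal tissue was not tested. Of the 25 with a partial return, 24 were higher and 1, Grin1, was lower. Among those 24 were the bulb list members Th, Calb2, Cdhr1, Sp8 and Pbx3, and among the 42 the merged model Doc2g,Nudt8. A different share of bulb tissue in the dissections may account for these, so they do not by themselves show a return of expression. Naming these list members does not clear the other models of these classes of such a share. Rmrp and Rpph1, also among the 42, carry no poly(A) tail, and poly(A) selection stays open for them. Another 7 (Nos1, Adamts2, Rxfp1, Penk, Tmem90a, Beta-s and a model of Hba-a1,Hba-a2) were called in rescue against both other groups and not in knockdown against wild type. Of 200 models higher in the knockdown with a mean FPKM of at least 1, 194 lay closer to wild type in rescue, with a median log2 fold of 0.45 in knockdown and 0.22 in rescue. Of 115 lower models 87 lay closer, with medians of -0.38 and -0.28. Shared knockdown values pull such counts toward return.

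Across 11625 models the folds of knockdown and rescue against wild type had a covariance of 0.0151 (r = 0.70, across genes, which are not independent replicates), and simulated unchanged groups with shared wild-type libraries gave r = 0.49 with either spread below. The same simulations gave a covariance of 0.0607 with the spread from the test statistic, which exceeds the variances of the folds themselves (0.0274 and 0.0168), and 0.0150 with the scaled spread added after seeing the data, whose variances of 0.0308 and 0.0306 also exceed those of the folds. The covariance exceeded the simulated one by at most 4.69e-05, while the correlation was higher than simulated. Since the simulated errors are too wide and assume equal error in each group, neither value shows or excludes shared changes across all genes.

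**Figure D3:**
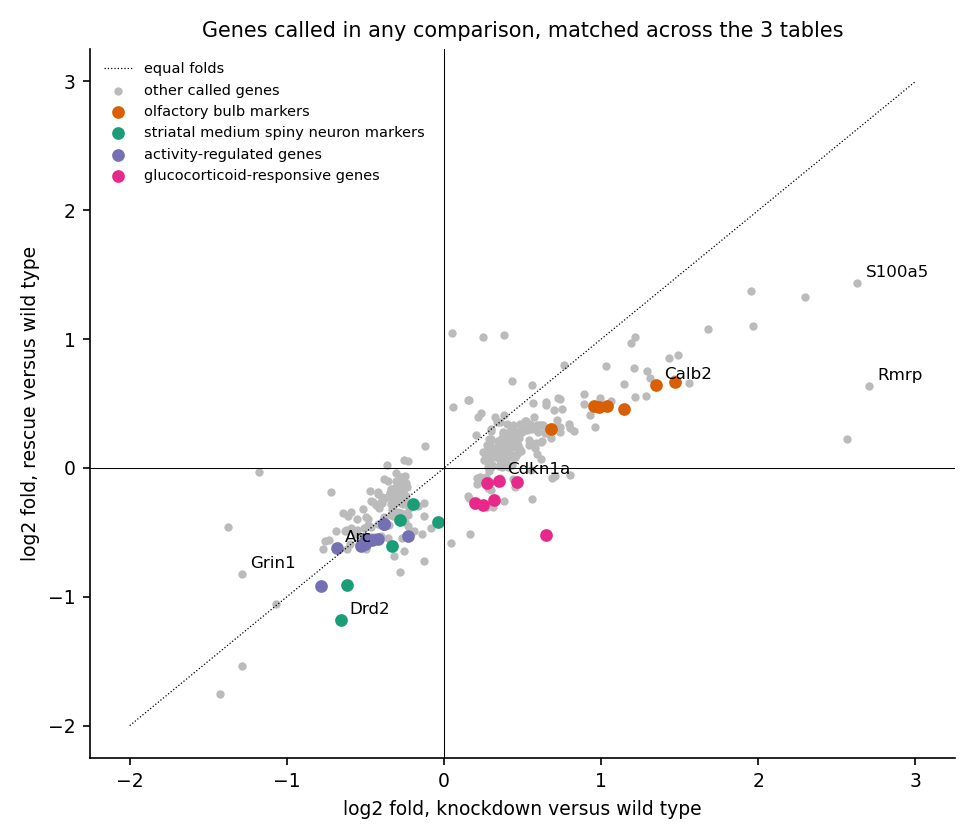
Log2 fold of rescue against wild type (vertical axis) and of knockdown against wild type (horizontal axis), with a point for each gene model called in any comparison and matched across the 3 tables, coloured by gene list, and a dotted line where both folds are equal. Bulb markers such as Calb2 (1.35 and 0.64) lie between the dotted line and the horizontal axis, while Arc (-0.68 and -0.62) lies near the line and Drd2 (-0.65 and -1.18) below it.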

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

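The tests of bulb tissue, of the interneuron and neuropeptide genes beside it, of histone genes, and without bulb and striatal list members were chosen after the result was seen; the tests of genes near Grin1 and near Gt(ROSA)26Sor and those of rescue against knockdown were planned.

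The comparison of rescue with knockdown is itself the test of the difference between their effects; Grin1 passed the authors' test in it, and the lists below held more called members than other genes by Fisher's exact test. Grin1 differed by 0.40 on the log2 scale, and 67 genes called in the knockdown were called oppositely in rescue against knockdown. The list medians in rescue against knockdown were -0.53 for olfactory bulb markers, -0.36 for glucocorticoid-responsive genes, -0.16 for interneuron markers, -0.16 for neuropeptides, -0.15 for astrocyte markers, -0.067 for hypothalamic and thalamic markers and 0.54 for blood cell markers. The hypothalamic and thalamic median lay at percentile 10.1 of matched random lists, so that list passed by its 2 called members only. Its call and that of interneuron markers were lost without bulb and striatal list members (adjusted p = 0.234 and 0.402, Fisher's exact test).

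Olfactory bulb markers stood higher than wild type in both groups, and a larger share of bulb tissue in those dissections may account for it. Gains were compared for 9 bulb markers, and 8 of them gained in both groups. The rescue gain was a median 0.375 of the knockdown gain, with an interquartile range of 0.108 over markers and a range of 0.349 to 1.39. The merged model Doc2g,Nudt8 was matched as well but left out of these ratios. Its log2 folds against wild type were 1.15 in knockdown and 0.46 in rescue. Bulb genes carried by tissue would gain in a common ratio, but under a genotype effect on the same cells they would too. The wild-type cortex expressed 11 of the list's models at 1 FPKM or more, and 1 list gene (Calb2) is also on other lists; the most abundant members went from 42.2 to 50.4 FPKM (Meis2) and from 62.1 to 58.2 FPKM (Gng13, at the top of that range, which was lower in both groups and whose high level in wild type would hide a small share). For the other 11 interneuron and neuropeptide genes called higher in the knockdown the median ratio was 0.541, between 0.153 and 0.859. These ratios did not pass a two-sided permutation test against the bulb markers (p = 0.106), which does not show a common source. The 8 of these bulb markers that gained lay between 0.349 (Th) and 0.476 (Pbx3), with Doc2g,Nudt8 left out. The other genes lay on both sides of that range, from 0.153 (Dlx5) to 0.859 (Adcyap1), which a single common ratio would not give. The error of each ratio is unknown without values per animal, so a common source stays open. Dissection and genotype cannot be told apart for the bulb markers without values per animal. The same holds for the striatal markers, for which the share of striatal tissue was not tested. An effect of Grin1 on inhibitory neurons stays open, untested.

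RNAs without a poly(A) tail stood higher in the knockdown than in either other group: Rmrp and Rpph1 by 2.71 and 2.56 against wild type, with Rn45s at 0.81. A candidate explanation is that more such RNA passed poly(A) selection in the knockdown libraries. Replication-dependent histone genes, a separate class without tails, had a median log2 fold of 0.61 over 19 models in knockdown against wild type, above 100% of matched random lists, with 18 of 19 positive; it was -0.35 over 18 models in rescue against knockdown, with 0 positive, and 0.29 over 16 models in rescue against wild type, with 15 positive, so the rescue libraries stood above wild type as well. The histone medians met the limits set for that test, but medians of 13 of the 32 gene lists also lay above the middle 95% in knockdown against wild type. Of the histone models 2 were called there and 0 in either other comparison. In rescue against wild type Rmrp and Rpph1 stood at 0.64 and 0.23 and were not called. The test therefore cannot tell poly(A) selection from other sources of these RNAs, and the technical explanation stands open. A biological change in these RNAs was not tested.

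In F1 hybrids of inbred strains, DNA linked to the targeted Grin1 allele or to the Cre insertion could differ between groups. Within 10 Mb of Grin1, 7 of 267 models were called in knockdown against wild type (odds ratio 1.04, 95% interval 0.413 to 2.2, p = 0.843, two-sided Fisher's exact test). The merged model Snhg7,Snora17,Snora43 lies in that window and was chosen after its values were seen. It was called lower than wild type in knockdown and rescue (log2 folds -1.29 and -1.53) and not called between them. Linked DNA stays open for it. Within 10 Mb of Gt(ROSA)26Sor on chromosome 6, 1 of 153 was called in rescue against wild type (odds ratio 0.774, 95% interval 0.0193 to 4.44, p = 1, two-sided Fisher's exact test). Neither interval excludes a few linked genes, and the labels do not name the Cre locus, so linked DNA cannot be told apart from the absence of it for these windows.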

How the results depend on the processing

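The tests with a rescaled or scaled spread, without marker genes, with single symbols only, or without bulb and striatal list members were chosen after the result was seen; the others were planned. Settings planned ahead left 179 values on the same side, within 1.5 times the reported count or, for median log2 folds, equal at 2 decimals, and those added later 75. Of the rest, 34 and 3 moved further, 22 and 10 lost their call and 1 and 3 were counted as a change of sign or direction. Median log2 folds that were not equal were counted as moved, also where their sign turned. The Grin1 folds kept their sign with a pseudocount, in TPM and centred, where no q was recomputed. No count near Grin1 or Gt(ROSA)26Sor passed the test in windows of 5 or 20 Mb or at q under 0.05, with odds ratios on both sides of 1. Without an adjustment, 1457, 773 and 797 genes had a p under 0.05 (knockdown against wild type, rescue against knockdown, rescue against wild type), with 304 in the opposite and 387 in the same direction across comparisons and classes of 217 (back), 296 (alike in both), 63 (rescue alone) and 82 (part of the way); looser calls give more by construction. With an absolute log2 fold of at least 0.5 the counts were 232, 76 and 92. With p from the deposited test statistic they were 41, 15 and 18, and with centred folds 42, 15 and 18 (33, 6 and 11 of them higher, against 306 of 464, 24 of 127 and 67 of 155), with overlaps of 2 and 5, classes of 1, 3, 0 and 1, and 4, 0 and 0 lists past the test. That statistic is about 0.497 of the normal deviate of the deposited p, which lowers such counts by construction; after rescaling they were 505, 146 and 180, and centred 516, 143 and 178. Median log2 folds were -0.0033 and -0.0056 without the FPKM filter (knockdown against wild type, rescue against knockdown). In TPM the medians of all comparisons turned from negative to positive, at 0.0112, 0.0183 and 0.0276. TPM adds the log2 ratio of the groups' summed FPKM to every fold. The excess covariance was -0.0248 at an FPKM of at least 5 and -0.0276 with a pseudocount, and turned from -0.0456 to 4.69e-05 with the scaled spread, whose smaller simulated errors show the cause. Without bulb and striatal list members 5, 4 and 3 lists passed, against 9, 7 and 8; that setting empties the bulb and striatal lists themselves, which were 2, 1 and 2 of those lost, and the GABA list kept its 3 called members and lost its call by the adjusted p (0.0663, Fisher's exact test). The median of neuropeptides in rescue against wild type, -0.0075, became 0.0041 with centred folds, with 0 members called by the deposited statistic and 7 by the rescaled one; centring adds the same value to every fold, so this says nothing of direction. It became 0.101 without bulb and striatal members, with 5 called. Without bulb, striatal and blood marker genes the calls were 449, 116 and 137. That setting removes only the genes on those lists, so these counts do not show how many other calls follow tissue share. No paired analysis was possible because the tables hold group values only; for the same reason the replicate block, leaving out each animal and other splits of the animals could not be run, and depth limits could not be set.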

Other observations

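The counts and medians here come from planned tests; the Snhg7 model was chosen after its values were seen.

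Vascular and stress lists held few calls, while most of their folds in the knockdown were positive. In knockdown against wild type, Vtn (vitronectin) was the 1 of 9 mural cell models that rose, Ly6a the 1 of 13 endothelial models, Hspa5 (an endoplasmic reticulum chaperone) the 1 of 26 heat shock and unfolded protein models and Srxn1 the 1 of 19 antioxidant models; 2, 5, 9 and 1 were called when adjusted over the list alone, at adjusted p of 0.406, 0.527, 0.703 and 0.636 (Fisher's exact test). Of their folds 9, 12, 18 and 11 were positive, and the medians of 0.20, 0.15, 0.12 and 0.03 lay at percentile 99.5 of matched random lists or above, and at 95.8 for the antioxidant list. In rescue against knockdown these lists had 0, 1 (Slc2a1, the glucose transporter GLUT1, lower), 0 and 0 calls, and against wild type 0 in each; adjusted over the list alone they had 0, 1, 0 and 0, then 0 in each. Their medians in rescue against wild type were 0.14, 0.13, 0.05 and 0.01, with 7 of 9, 10 of 12, 18 of 26 and 10 of 19 folds positive. These medians lay at percentile 99.78 of matched random lists or above, and at 93.0 for the antioxidant list. The water channel Aqp1 was the 1 of 3 choroid plexus models called in each comparison, at log2 folds of 1.43, -0.53 and 0.85 for knockdown against wild type, rescue against knockdown and rescue against wild type, with 2, 1 and 1 called when adjusted over the list alone (adjusted p = 0.208, 0.0951 and 0.0921, Fisher's exact test). Blood cell markers in knockdown against wild type had 1 of 7 called, a model of Hba-a1,Hba-a2 at 0.38, and 1 when adjusted over the list alone (adjusted p = 0.345, Fisher's exact test).

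Oligodendrocyte, microglia and metabolic lists were nearly without calls by Cuffdiff. Opalin, a myelin gene, was the 1 of 20 oligodendrocyte models that fell in the knockdown, and 2 were called when adjusted over the list alone (adjusted p = 0.636, Fisher's exact test); rescue had 0 calls against either group, and 0 adjusted over the list alone. In rescue against knockdown 16 of 20 oligodendrocyte folds were negative, with the median at percentile 0.03 of matched random lists. Oligodendrocyte precursor (8 models), microglia (16), interferon (12) and sex-linked (4) lists had 0 calls in all 3 comparisons. Adjusted over the list alone, precursor genes had 1, 1 and 0, and the others 0. Of the precursor folds 8, 1 and 6 were positive in the 3 comparisons, with medians at percentiles 99.2, 0.94 and 98.2. Of the interferon folds 11, 7 and 9 were positive, at percentiles 98.7, 85.9 and 99.6. Microglia and sex-linked medians lay within the middle 95%. Per1 was the 1 circadian gene that fell, among 16 in the knockdown and 15 in rescue against wild type, with 2 and 3 called when adjusted over the list alone, and 0 of 16 in rescue against knockdown. Of nuclear oxidative phosphorylation models, 0 of 74, 73 and 74 were called in the 3 comparisons over all genes or adjusted over the list alone, with medians of -0.01, -0.05 and -0.07. Of these folds 39, 60 and 68 were negative, and the medians lay at percentiles 97.2, 0 and 0.1 of matched random lists. Cytosolic ribosomal proteins had 0 of 68, 1 of 66 and 1 of 69 called, the model of Rplp2 in both, and as many when adjusted over the list alone. Their medians of -0.05, -0.02 and -0.07 lay at percentiles 0.33, 20.6 and 0, with 48, 37 and 54 negative folds. For scale, Cuffdiff gave 1457, 773 and 797 models an unadjusted p under 0.05.

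A merged model of the non-coding genes Snhg7,Snora17,Snora43 on chromosome 2 (26636918 to 26640260), near Grin1, stood at a log2 fold of -1.29 in knockdown and -1.53 in rescue against wild type. It was called in both (q = 0.00456 and 0.0098 in the authors' deposited tables). Between rescue and knockdown its log2 fold was -0.01 and it was not called.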
